A study of Rattus norvegicus with 18 samples.

How the data were processed

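Total RNA from placentas of Long Evans rats was hybridised to Affymetrix Rat Gene 2.0 ST arrays, per the labels' protocols: a part of each placenta was used, RNA was extracted with TRIzol and a spin column kit and biotinylated cRNA was prepared by the manufacturer's standard method. Per the submitters' processing notes the values were made with Affymetrix Expression Console and RMA (robust multi-array average, which corrects background, normalizes quantiles across arrays and summarises the probes of each transcript cluster); no version is given in the sources used here. The deposited values are on the log2 scale, as the file's values show, running from 1.61 to 13.6 over 36685 rows and 18 arrays. RMA sets all arrays to nearly the same distribution, so a change of the same size in all genes would not be seen, and quantile normalization can spread the deviation of a poor sample over many genes. No filter on signal above background is stated. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

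Rows were named through the platform annotation. Of the rows, 18511 had 1 gene symbol, 575 had several and were not used, and 17599 were unnamed in that annotation. Symbols were updated by Entrez ID through a RefSeq gene table of the GRCr8 assembly, in which 18394 of the singly named rows were found, with 0 symbols changed. For the 291 genes with more than 1 row, the row with the highest mean over all arrays was used, which gave 18166 genes. The 190 control rows served only to check the arrays: 39 detect poly-A spike-ins and 151 others include 23 background rows.

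Groups were taken from the sample labels, 6 arrays in each. Genes were tested with limma 3.58.1 in R 4.3.3: a linear model of the 3 group means over all 18 arrays, empirical Bayes moderation, 3 pairwise contrasts and an F test, with Benjamini-Hochberg adjustment over all genes and an adjusted p below 0.05 as the threshold. Of 40 gene lists fixed before the data were examined, 39 had at least 5 measured members and were tested with camera at its preset correlation of 0.01, two-sided, with adjustment over the lists of each comparison; 796 genes belonged to a tested list. Camera compares a list with all other genes; fry tests whether the genes of a list move, on balance, in 1 direction. Because camera's preset correlation is low for genes that vary together between placentas, each list was also tested with an estimated correlation and by an exact two-sided permutation test of its mean per array relative to the array's mean over all genes. With 6 arrays against 6 there are 924 assignments, and the smallest p that test can give is 0.00216.

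The genes named were set by a rule fixed before the data were examined: with fewer than 24 genes past the threshold, all of those plus the genes with the smallest unadjusted p up to 20 in all, the 4 members with the smallest unadjusted p of each list called by camera, at most 2 of other lists, and the fetal sex genes. Predicted genes of unknown function, recognised by provisional symbols only, and olfactory and vomeronasal receptor genes were passed over. The position of VSG between the sham groups was measured on the 200 genes with the smallest p between obese and lean sham, and set against 40 random regroupings of the arrays and against splits of the obese sham arrays.

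Alternatives fixed in advance were every transcript cluster on its own, all rows, filters at a mean of 5 (14419 genes) and at the median gene, a second quantile normalization, centring on each array's median, trend and robust moderation, array weights, only the compared groups, the replicate number as a block, the level of Uty as a covariate (planned for fetal sex, which its level did not resolve), a threshold of 0.1, an unadjusted threshold with a fold of 1.5, and each array left out in turn. Chosen after seeing the data were the exact permutation test of lists, the array set as a block with and without obese sham replicate 5, and the yolk sac list as a covariate. Shifts of single lists without each array were read from the same refits. The array set was read from the first principal component of the 151 control rows, which took 43.7% of their variance over 17 arrays; no label names a hybridisation batch. No arrays were identical, the highest correlation between any pair being 0.9897.

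The gene and list tests were run on simulated data with the real means and residual spreads and independent genes. For obese sham against lean sham, 18 of 50 genes changed by 0.5 on the log2 scale were recovered and 44 of 50 changed by 1; for VSG against obese sham 14 and 44 of 50; for VSG against lean sham 21 and 46 of 50. Each simulation changed 50 genes by 0.5, 50 by 1, 50 by 1.5 and 50 by 2 at once. The adjustment is more lenient where many genes change, so these rates need not hold where few do. No array sets and no single outlying array were simulated. A list shifted by 0.3 was called in each, with 0 other lists called. Because the simulated genes were independent, this could not show false list calls from genes that vary together. Random splits of the real arrays called a median of 14, 14 and 8 lists in the 3 comparisons. False calls among the unchanged genes numbered 13, 8 and 10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.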

Results

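The series measured gene expression in placentas of Long Evans rats with whole-transcript microarrays, 1 array per sample. The 18 arrays fell into 3 groups of 6: lean rats that had a sham operation (lean sham), obese rats that had a sham operation (obese sham), and rats that had VSG, the abbreviation used for vertical sleeve gastrectomy, an operation that removes most of the stomach. The labels do not give the diet or the body weight of the VSG rats. The females were mated at 21 weeks of age, and the age given for the samples is 24 weeks. Placentas were taken preferably from uterine positions 3 and 4. The titles call the samples biological replicates and do not say whether each came from a different dam, so the p-values measure the spread between these samples. In all, 18166 named genes and 39 gene lists were tested, and the number of arrays limits the precision: the median standard error of a difference between groups was 0.143 on the log2 scale.

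The arrays differed in ways that no label names and that were spread unevenly over the groups. Obese sham replicate 5 correlated with the other arrays at r = 0.851 to 0.888, while the other 17 arrays correlated among themselves at 0.961 or more. In that array 2582 genes lay over 2-fold below the mean of the other obese sham arrays and 1208 lay over 2-fold above it, and its poly-A spike-in rows, which detect bacterial control transcripts added to each sample, averaged 8.65 on the log2 scale. The first principal component of the 151 control rows other than those spike-in rows divided the arrays into a set of 12 (set 1) and a set of 6 (set 2). Whether any of these rows detect rat RNA was not checked. Set 2 held 2 lean sham (replicates 5 and 6), 1 obese sham (replicate 6) and 3 VSG arrays (replicates 4 to 6), the highest numbers of each group. With the groups as terms and obese sham replicate 5 left out, 7068 genes differed between the sets (limma, adjusted p below 0.05), 3490 of them higher in set 2. Values within the sets are therefore given beside the main list results.

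**Figure D1:**
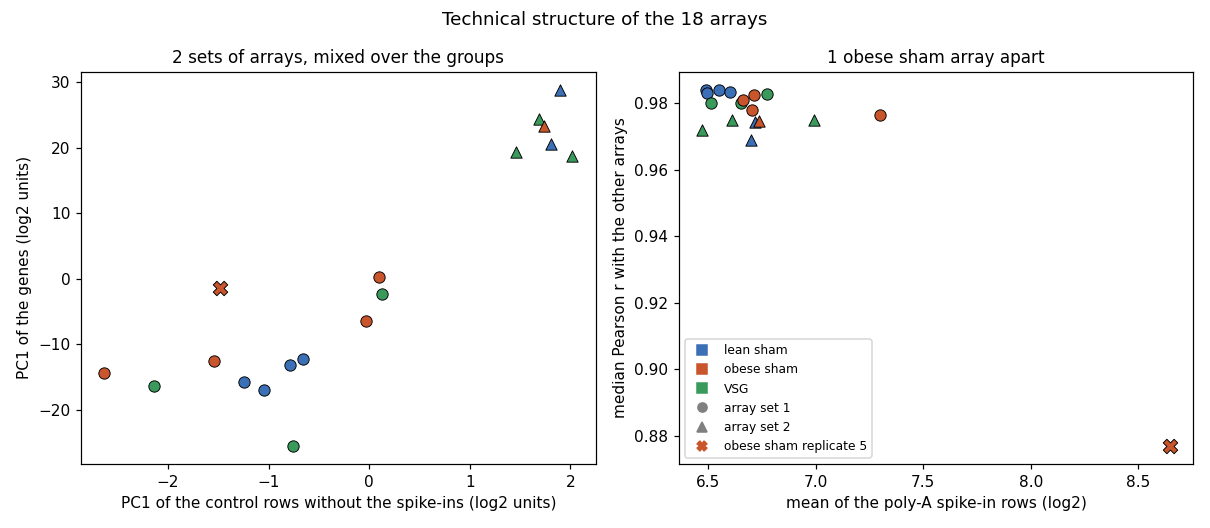
Each point is 1 of the 18 arrays, coloured by group. Left, the first principal component of the control rows without spike-ins against that of the genes (log2 units), fitted on 17 arrays with obese sham replicate 5 projected: the 6 arrays of set 2 lie above every set 1 array on the gene axis. Right, the mean of the poly-A spike-in rows (log2) against the median Pearson r with the other arrays: obese sham replicate 5 sits at 8.65 and 0.877.

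The first comparison, obese sham against lean sham, asked what accompanied maternal obesity in placentas of rats without the gastrectomy. As lists, red cell genes were lower in obese sham placentas, and genes of the ribosome, the respiratory chain and the yolk sac were higher. In all 13 lists were called, where random splits of the same arrays called a median of 14. All 15 measured erythroid genes were lower, and their mean fell by 0.29 on the log2 scale relative to the other genes (camera, adjusted p = 0.000457; adjusted p = 0.788 with an estimated correlation). Among them the erythroid transcription factor Gata1 differed by -0.52 ± 0.20 (log2 difference ± SE), Klf1, another such factor, by -0.23 ± 0.10, the red cell membrane protein gene Sptb by -0.56 ± 0.26, and the anion exchanger Slc4a1 by -1.20 ± 0.56, or by -0.68 without obese sham replicate 5. All 27 measured genes of the cytosolic ribosome were higher, by 0.25 relative to the other genes (adjusted p = 3.18e-08, and adjusted p = 0.788 with an estimated correlation), with Rpl6 at 0.30 ± 0.10 and Rps19 at 0.48 ± 0.21. Of the 32 respiratory chain genes 29 were higher, by 0.20 (adjusted p = 2.75e-06, and 0.788 as the adjusted p with an estimated correlation), among them Ndufb3 at 0.35 ± 0.13 and Atp5po at 0.38 ± 0.17. Without obese sham replicate 5 the ribosome list was at 0.11, the respiratory chain at 0.08, Rps19 at 0.24 and Atp5po at 0.20, and both lists were past the test. The other obese sham arrays averaged 6.66 to 7.3 on the poly-A spike-in rows, against 6.49 to 6.72 in lean sham. The spike-in mean was not fitted as a term in this comparison, so less or degraded RNA cannot be told apart from obesity here. The yolk sac endoderm list, markers of the membrane that borders the placental disc, was higher by 0.58 with 17 of 22 members higher (adjusted p = 0.0335, and adjusted p = 0.883 with an estimated correlation): transthyretin (Ttr) differed by 1.83 ± 0.79 and alpha-fetoprotein (Afp) by 1.89 ± 0.85. Lean sham replicate 5 was far above the other lean sham arrays on this list, and without it the shift was 1.08. The call was lost, at shifts of 0.306 to 0.57, without any 1 of lean sham replicates 1, 3, 4 and 6 or obese sham replicates 1, 2, 3 and 6.

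Glucose and amino acid transporters fell by 0.32 relative to the other genes, with 23 of 26 lower (adjusted p = 2.75e-06; adjusted p = 0.788 with an estimated correlation), and by 0.11 without obese sham replicate 5. The glucose transporter Slc2a12 differed by -0.58 ± 0.24, the taurine transporter Slc6a6 by -0.61 ± 0.26 and the cationic amino acid transporter Slc7a2 by -0.57 ± 0.29, or by -0.37, -0.28 and -0.20 without that array. The prolactin family, hormones of the trophoblast, was higher by 0.16 with 17 of 20 members higher (adjusted p = 0.00393), Prl8a9 at 0.26 ± 0.12. Imprinted placental genes fell by 0.23, with 17 of 22 lower (adjusted p = 0.00295), Zim1 at -0.48 ± 0.18 and the organic cation transporter Slc22a3 at -0.54 ± 0.24. With an estimated correlation the adjusted p was 0.788 for both lists. Endothelial genes fell by 0.21 (11 of 13 lower, adjusted p = 0.0126) and circadian clock genes fell by 0.17 (13 of 15 lower, adjusted p = 0.0047), each with an adjusted p of 0.788 with an estimated correlation. Labyrinth trophoblast genes fell by 0.24 (17 of 20 lower, adjusted p = 0.00369), extracellular matrix genes by 0.21 (24 of 29 lower, adjusted p = 0.0126) and insulin and IGF axis genes by 0.16 (18 of 25 lower, adjusted p = 0.0232). With an estimated correlation the adjusted p was 0.8 for the labyrinth and 0.814 for the matrix and insulin lists. All 7 of these calls were lost without obese sham replicate 5, at 0.05 for the prolactin family, -0.05 for imprinted genes, -0.03 for endothelium, -0.02 for the clock, 0.02 for the labyrinth, 0.07 for the matrix and 0.08 for the insulin list. Prl8a9, Zim1 and Slc22a3 were at 0.17, -0.27 and -0.30 without that array. The prolactin family was at 0.258 and the matrix at -0.343 without obese sham replicate 1. In obese sham replicate 5 the amino acid transporter Slc7a5 read 7.76 against 11.2 or more in the other obese sham arrays, and fibronectin (Fn1) read 9.72 against 12.8 or more. The matrix and insulin calls were also lost without lean sham replicate 5, at -0.171 and -0.127. The neutrophil and granulocyte list was higher by 0.18 with 14 of 18 members higher (adjusted p = 0.0172; adjusted p = 0.788 with an estimated correlation), a call lost at 0.126 to 0.157 without any 1 of lean sham replicates 5 and 6 or obese sham replicates 1 and 2.

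Of these 13 lists, 5 higher and 8 lower, 6 were past the test in the same direction without obese sham replicate 5: erythroid cells (-0.28), ribosome, respiratory chain, yolk sac (0.86), transporters and neutrophils (0.13). Lists called only without that array were immediate early genes, which can mark tissue handling (0.119, adjusted p = 0.029, against -0.00828 over all arrays), and junctional zone and glycogen trophoblast genes (0.0808, adjusted p = 0.0399). With an estimated correlation their adjusted p was 0.782 and 0.706. Within set 1 and set 2, the latter with 1 obese sham array, the erythroid list differed by -0.18 and -0.48, the ribosome by 0.30 and 0.09, the respiratory chain by 0.25 and 0.08, the yolk sac by 0.98 and 0.11, the transporters by -0.31 and -0.23 and the neutrophils by 0.09 and 0.24. Set 1 held obese sham replicate 5, and without it the set 1 values were -0.165, 0.125, 0.101, 1.29, -0.0632 and 0.044. With the array set as a block the shifts were -0.29, 0.25, 0.22, 0.72, -0.31 and 0.14, the neutrophil and insulin calls were lost (adjusted p = 0.0861 and 0.0537), and macrophages, lower, were gained (adjusted p = 0.0494, and 0.788 over all arrays with an estimated correlation). An exact two-sided permutation test of the list means per array, 6 against 6, gave p = 0.00866 for the transporters, lower in 6 of 6 obese sham arrays, and no adjusted p below 0.338. None of the 35 list calls in the 3 comparisons held with an estimated correlation.

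No single gene passed the test in this comparison (limma, smallest adjusted p = 0.798), while 618 genes had an unadjusted p below 0.05, where 908.3 would be expected by chance from independent tests, 347 of them higher and 271 lower in obese sham. That count was 453 without obese sham replicate 5, with 187 higher and 266 lower. It was 992 without obese sham replicate 6 and 413 with only the 2 groups in the model. Among genes not passed over by the naming rule, the following 20 had the smallest unadjusted p and did not pass. Map1a, a microtubule-associated protein, differed by -0.61 ± 0.15, the potassium channel gene Kcnk6 by -0.74 ± 0.20, catalase (Cat) by -0.47 ± 0.14, the inhibin and activin subunit Inhba by -0.64 ± 0.19, the ferric reductase Frrs1 by -0.64 ± 0.19 and Pcyt1b, an enzyme of phosphatidylcholine synthesis, by -0.61 ± 0.19. Dph6, Asb13 and Cpeb3 lay between -0.44 and -0.39. On the higher side, the ribosomal protein genes and near-copies Rps15al4, Rpl23al4, Rpl12l2, Rpl8l1, Rps10l2 and Rps28 lay between 0.30 and 0.61, and their probes can share sequence with their parent genes. Npm1-ps9 (0.59 ± 0.18), Hmgn2l1 (0.55 ± 0.15), Sectm1b (0.40 ± 0.12), the fatty acid hydroxylase Cyp4a8 (0.38 ± 0.12) and Bod1 (0.35 ± 0.10) completed the list. Rps10l2, Cyp4a8, Pcyt1b and Hmgn2l1 had no group mean above 5.224 (log2). Background control rows averaged 4.577 to 5.015 over the arrays, so differences in these genes may be noise near the floor. Relative to the lean sham mean, the direction held in all 6 obese sham arrays for 18 of the 20, and in 5 for Inhba and Frrs1. Choosing genes by p in the same arrays makes such agreement likely, so it is not separate evidence.

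The comparison of VSG with obese sham asked what set placentas after the gastrectomy apart from those of the obese sham controls. Genes of vessels, transport and the decidua were higher in VSG placentas as lists. In all 12 lists were called here, where random splits of the same arrays called a median of 14. All 13 endothelial genes were higher, by 0.30 relative to the other genes (camera, adjusted p = 0.000251; adjusted p = 0.662 with an estimated correlation), including the endothelial nitric oxide synthase Nos3 at 0.26 ± 0.13, the transcription factor Erg at 0.33 ± 0.16 and the receptor Tie1 at 0.57 ± 0.29. Glucose and amino acid transporters rose by 0.30, with 22 of 26 higher (adjusted p = 9.53e-05; adjusted p = 0.662 with an estimated correlation), Slc2a12 at 0.53 ± 0.24 and Slc7a2 at 0.61 ± 0.29. Decidual stroma genes rose by 0.19, with 15 of 21 higher (adjusted p = 0.0074; adjusted p = 0.662 with an estimated correlation), the progesterone receptor Pgr at 0.93 ± 0.33 and Bmp2, a signal of decidualisation, at 0.53 ± 0.22. Hypoxia and glycolysis genes rose by 0.18, with 12 of 18 higher (adjusted p = 0.00481; adjusted p = 0.662 with an estimated correlation), the glycolytic enzymes Pfkp at 0.59 ± 0.22 and Hk2 at 0.54 ± 0.29. Without obese sham replicate 5 these 4 lists were past the test at 0.12, 0.09, 0.09 and 0.09, and Tie1, Slc7a2, Pgr and Hk2 were at 0.20, 0.25, 0.59 and 0.18. Nos3, Erg, Slc2a12, Bmp2 and Pfkp were at 0.15, 0.19, 0.32, 0.32 and 0.34 without that array. Interferon response genes rose by 0.15, with 18 of 24 higher (adjusted p = 0.00435; adjusted p = 0.677 with an estimated correlation), among them the antiviral GTPase Mx2 at 0.33 ± 0.13 and the interferon-induced GTPase Gbp5 at 0.49 ± 0.23. The interferon call was lost without VSG replicate 5 (0.0635, with Gbp5 at 0.30), and the shift was 0.238 without VSG replicate 2.

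Another 7 lists were called over all arrays and lost without obese sham replicate 5. Angiogenic factors rose by 0.20, with 12 of 17 higher (adjusted p = 0.00435; adjusted p = 0.662 with an estimated correlation): Angpt2, a ligand of the endothelial receptor Tek, differed by 0.40 ± 0.13 and placental growth factor (Pgf) by 0.64 ± 0.31, while hepatocyte growth factor (Hgf) differed by -0.24 ± 0.11. Hgf had no group mean above 5.022 (log2), near the level of the background control rows. Circadian clock genes rose by 0.21 with 15 of 15 higher (adjusted p = 0.000436; adjusted p = 0.662 with an estimated correlation), Clock at 0.48 ± 0.20 and Bmal1 at 0.22 ± 0.12. Extracellular matrix genes rose by 0.26 (25 of 29 higher, adjusted p = 0.0029), insulin and IGF axis genes by 0.21 (21 of 25 higher, adjusted p = 0.0029) and labyrinth trophoblast genes by 0.24 (15 of 20 higher, adjusted p = 0.00481). With an estimated correlation the adjusted p was 0.749 for all 3 lists. Their members nidogen (Nid1), Igf1r and the gap junction gene Gjb2 differed by 0.83 ± 0.47, 0.51 ± 0.30 and 0.36 ± 0.17, or by 0.20, 0.12 and 0.14 without obese sham replicate 5, where Clock was at 0.25. The cytosolic ribosome fell by 0.18 with 23 of 27 lower (adjusted p = 0.000308) and the respiratory chain fell by 0.15 with 29 of 32 lower (adjusted p = 0.000803), both with an adjusted p of 0.749 with an estimated correlation. Without obese sham replicate 5 the angiogenic list was at 0.09, the clock at 0.06, the matrix at -0.03, the insulin list at -0.03, the labyrinth at -0.02, where the camera test pointed up, the ribosome at -0.03 and the respiratory chain at -0.03. The matrix shift was 0.385 without obese sham replicate 1, and the respiratory chain call was also lost without VSG replicate 2 (-0.106).

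Of these 12 lists, 10 higher and 2 lower, the first 5 were thus past the test in the same direction without obese sham replicate 5. The spike-in mean was not fitted as a term in this comparison either. The yolk sac list, at -0.45 with an adjusted p of 0.0539 over all arrays, was at -0.72 without that array (adjusted p = 3.22e-06), cholesterol synthesis genes were at -0.15 (adjusted p = 0.0029) and antigen presentation genes at 0.10 (adjusted p = 0.0457), with adjusted p = 0.659 or more for every list with an estimated correlation. Lean sham replicate 5 and obese sham replicate 1 read highest of all arrays on both the yolk sac list (3.227 and 2.675) and the cholesterol list (1.441 and 1.219). The yolk sac and cholesterol shifts may therefore not be separate. Differences within set 1 and set 2, the latter with 1 obese sham array, were 0.38 and 0.12 for the endothelium, 0.36 and 0.08 for the transporters, 0.26 and 0.09 for the decidual stroma, 0.21 and 0.04 for hypoxia and glycolysis, and 0.02 and 0.17 for the interferon response. Set 1 values without obese sham replicate 5 were 0.16, 0.113, 0.144, 0.103 and 0.0304. With the array set as a block they were shifted by 0.30, 0.27, 0.24, 0.16 and 0.06, and the interferon call was lost (adjusted p = 0.101). The block brought further lists past the test: yolk sac (adjusted p = 0.000279), cholesterol synthesis (0.000485), prolactin family (0.034), fatty acid oxidation (0.0203) and cell cycle (0.0422) pointed down, and immediate early genes (0.00465), antigen presentation (0.0136), macrophages (0.0203) and inflammation (0.0203) up. With an estimated correlation over all arrays none of these had an adjusted p below 0.662. The exact permutation tests gave no adjusted p below 0.646.

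**Figure D2:**
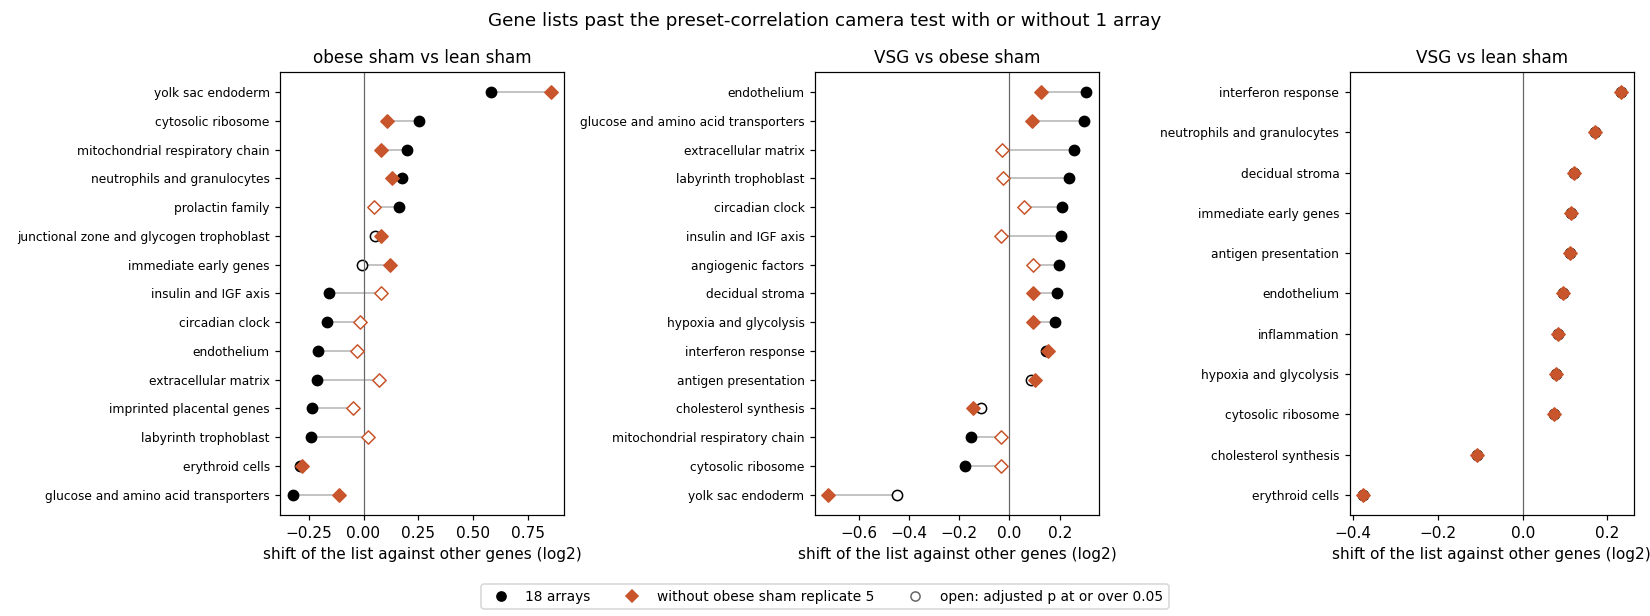
Shift of each gene list relative to the other genes (log2, horizontal axis) in the 3 comparisons, over 18 arrays (black circles) and without obese sham replicate 5 (orange diamonds); filled symbols had an adjusted p below 0.05 in the camera test. Lists past the test in either setting are drawn. In both comparisons with obese sham many shifts shrink or cross 0 without that array, and the yolk sac shift grows from 0.58 to 0.86 and from -0.45 to -0.72.

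No gene passed the test between VSG and obese sham either (limma, smallest adjusted p = 0.73); 713 genes had an unadjusted p below 0.05, 342 higher and 371 lower in VSG. The count of 713 was 371 without VSG replicate 4, 434 without VSG replicate 6 and 409 with only the 2 groups in the model. It was 448 without obese sham replicate 5, with 268 higher and 180 lower, and 1396 without obese sham replicate 6. Among the 20 with the smallest unadjusted p, the leukocyte common antigen gene Ptprc differed by 0.73 ± 0.18, Col15a1, a collagen of basement membranes, by 0.77 ± 0.19, and Cybb, the phagocyte oxidase subunit, by 0.35 ± 0.11. Itga2, a collagen-binding integrin subunit, differed by 0.97 ± 0.30, or 0.68 without obese sham replicate 5. Inhba and Map1a, both lower in obese than in lean sham placentas, differed by 0.74 ± 0.19 and 0.54 ± 0.15 here, a comparison that shares the obese sham arrays with the previous one. Mid2, Ablim3, Cep97 and Loxl3 lay between 0.27 and 0.42. The thiosulfate sulfurtransferase Tst differed by -0.66 ± 0.20, Rps10-ps22 by -0.53 ± 0.14, Pinlyp by -0.50 ± 0.14, the glutamate receptor subunit Grik2 by -0.43 ± 0.11 and the integrin ligand Edil3 by -0.34 ± 0.09. Fabp9, Sectm1b, Mlph, Dydc1 and Sec14l2 lay between -0.44 and -0.35. Edil3, Rps10-ps22, Fabp9, Dydc1 and Sec14l2 had no group mean above 4.975 (log2). Background control rows averaged 4.577 to 5.015 over the arrays, so differences in these genes may be noise near the floor. Relative to the obese sham mean, all 20 differences had the same direction in all 6 VSG arrays, which the choice by p in these arrays makes likely.

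VSG placentas were then set against lean sham placentas. Genes of interferon response and antigen presentation were higher and red cell genes lower in VSG. In all 10 lists were called, where random splits of the same arrays called a median of 8. Of 24 interferon response genes 21 were higher, by 0.23 relative to other genes (camera, adjusted p = 2.87e-09; adjusted p = 0.23 with an estimated correlation): Gbp5 differed by 0.77 ± 0.23, Mx1 by 0.49 ± 0.19, Mx2 by 0.31 ± 0.13 and Ifit3 by 0.34 ± 0.16. The list stood at 0.774 ± 0.281 in VSG and 0.543 ± 0.166 in lean sham relative to the mean of all genes (log2, mean ± SD, n = 6 each). Antigen presentation genes rose by 0.11, with 11 of 16 higher (adjusted p = 0.00475; adjusted p = 0.141 with an estimated correlation). Cd74, the invariant chain of MHC class II, was at 7.12 ± 0.45 against 6.46 ± 0.25 (log2, SD), and Psmb8 of the immunoproteasome, the class II gene RT1-Da and the peptide transporter Tap1 differed by 0.34 ± 0.15, 0.28 ± 0.15 and 0.26 ± 0.14 (SE), Tap1 by 0.16 without VSG replicate 3. The antigen presentation list was above the lean sham mean in 6 of 6 VSG arrays and the interferon list in 5. The exact two-sided permutation test of the list mean gave p = 0.013 for antigen presentation and p = 0.108 for the interferon response (0.507 and 0.819 after adjustment over 39 lists). Within set 1 and set 2 the differences were 0.16 and 0.22 for the interferon response and 0.12 and 0.13 for antigen presentation. With the array set as a block they were shifted by 0.19 and 0.13. The interferon shift was 0.148 without VSG replicate 5, and the antigen presentation call was lost without lean sham replicate 5 (0.0915, adjusted p = 0.0589) or VSG replicate 2 (0.102, adjusted p = 0.0506).

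All 15 erythroid genes were lower in VSG than in lean sham, and the list fell by 0.38 (adjusted p = 1.17e-10; adjusted p = 0.248 with an estimated correlation), with the beta globin Hbb-b1 at -0.60 ± 0.25, the embryonic globin Hbe1 at -0.67 ± 0.31 and the Rhesus gene Rhd at -0.43 ± 0.24. That list varied widely between VSG arrays, at 1.29 ± 0.55 (log2, SD, n = 6) against 1.67 ± 0.23 in lean sham. VSG replicates 1 and 5 read lowest, at 0.759 and 0.729, where the other VSG arrays read 1.34 or more. Of the VSG arrays these also had the highest poly-A spike-in means (6.77 and 6.99) and interferon list means (0.841 and 1.19). It differed by -0.09 in set 1 and by -0.79 in set 2, by -0.38 with the set as a block, and by -0.567 without VSG replicate 3. Neutrophil and granulocyte genes rose by 0.17 with 10 of 18 higher (adjusted p = 0.00465; adjusted p = 0.737 with an estimated correlation), Mmp8 at 0.90 ± 0.36, S100a9 at 0.76 ± 0.31 and Cxcr2 at 0.39 ± 0.18. Inflammation genes rose by 0.08 with 19 of 26 higher (adjusted p = 0.0277; adjusted p = 0.737 with an estimated correlation): the interleukin receptor antagonist Il1rn differed by 0.68 ± 0.19 and the chemokine Ccl2 by 0.31 ± 0.19, while Il18 differed by -0.43 ± 0.22, or by -0.22 without lean sham replicate 5. Cholesterol synthesis genes fell by 0.11 with 16 of 19 lower (adjusted p = 0.0277; adjusted p = 0.888 with an estimated correlation), Dhcr7 at -0.36 ± 0.23 and the regulator Srebf2 at -0.29 ± 0.24. This list differed by 0.01 in set 1 and by -0.38 in set 2, and was at 0.01 without lean sham replicate 5, where Dhcr7 was at -0.17. The remaining calls were decidual stroma (0.12, adjusted p = 0.0378, Gja1 at 0.31 ± 0.20) and hypoxia and glycolysis (0.08, adjusted p = 0.0399), each with an adjusted p of 0.737 with an estimated correlation. Immediate early genes, which can mark tissue handling (0.11, adjusted p = 0.0399), and the cytosolic ribosome (0.07, adjusted p = 0.0315) had an adjusted p of 0.904 with an estimated correlation. With the array set as a block the hypoxia call was lost (adjusted p = 0.115), and fatty acid and triglyceride synthesis, lower, and uterine smooth muscle, higher, were gained (adjusted p = 0.00625 and 0.0265, and 0.904 and 0.888 over all arrays with an estimated correlation). Endothelial genes were called only without obese sham replicate 5 (0.0947, adjusted p = 0.0181, and adjusted p = 0.593 with an estimated correlation). Without lean sham replicate 5 or 6, or VSG replicate 1, 2 or 3, the number of calls fell from 10 to 6, 6, 4, 6 and 3. Leaving out any 1 of those 5 arrays ended the cholesterol call (-0.106 to 0.00703) and the decidual call (0.05 to 0.127). The same held, except for VSG replicate 2, for the neutrophil call (0.119 to 0.141). The immediate early call was lost without any 1 of those 5 or lean sham replicate 4 (0.0488 to 0.115). The inflammation call was lost without any 1 of those 6 or VSG replicate 5 (0.0436 to 0.0805). The ribosome call was lost without any 1 of lean sham replicates 2, 4 and 5 or VSG replicates 1, 3, 5 and 6 (0.0364 to 0.0804). The hypoxia call was lost without any 1 of lean sham replicates 1, 2, 4 and 6 or VSG replicates 2, 3, 4 and 6 (0.0595 to 0.0776). Decidual stroma was at 0.05 without lean sham replicate 6, immediate early genes at 0.0488 without VSG replicate 1, and inflammation and the ribosome at 0.0436 and 0.0364 without VSG replicate 3. Hypoxia and inflammation were at 0.124 without lean sham replicate 5 and 0.126 without lean sham replicate 3. Macrophage, natural killer, T and B cell lists were not called, at 0.02, -0.01, -0.04 and -0.00026, with adjusted p = 0.924, 0.924, 0.161 and 0.977. For macrophages the median was -0.02 and the camera test pointed down, and for B cells it pointed up.

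**Figure D3:**
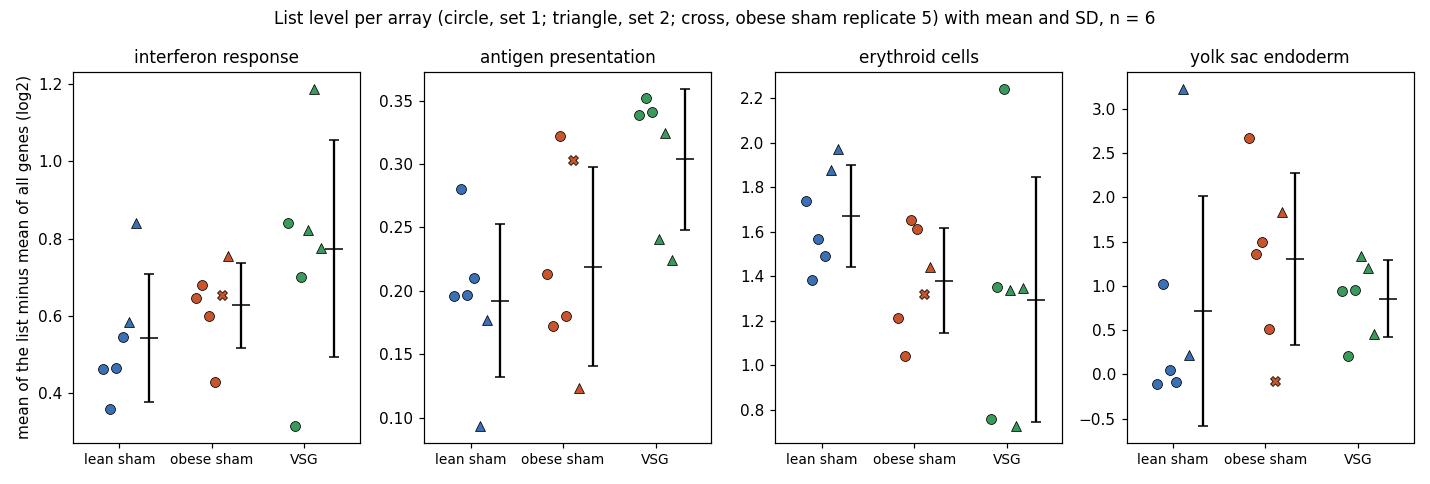
Mean of 4 gene lists minus the mean of all genes (log2, vertical axis) in each array of the 3 groups; circles are set 1, triangles set 2 and the cross obese sham replicate 5, with the mean and SD (n = 6) beside each group. The antigen presentation list lies above the lean sham mean of 0.192 in 6 of 6 VSG arrays, and the yolk sac list reads 3.23 in lean sham replicate 5, where the other lean sham arrays read 1.02 or less.

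No gene passed the test between VSG and lean sham (limma, smallest adjusted p = 1), and 182 genes had an unadjusted p below 0.05, 96 higher and 86 lower in VSG. The count of 182 was 284 or 276 without lean sham replicate 5 or 6, 345 without VSG replicate 2, 403 without obese sham replicate 5 and 389 with only the 2 groups in the model. Over the inflammation list alone, Il1rn passed, and over the antigen presentation list alone, Cd74 passed (1 gene adjusted over the list alone in each, 0 over all genes tested). No member of the other called lists passed adjusted over the list alone in any of the 3 comparisons. The 20 genes with the smallest unadjusted p, none of which passed over all genes, began with Cd74 (0.67 ± 0.17), followed by Gpr15lg, a ligand of a lymphocyte homing receptor (0.72 ± 0.19), Acnat1 (0.57 ± 0.16), Il1rn and the lymphocyte chemokine Cxcl13 (0.99 ± 0.29). Cripto, a coreceptor of Nodal signalling, differed by 0.61 ± 0.20, the interferon-induced gene Samd9l by 0.57 ± 0.19, the lectin gene Cd209fl1 by 0.46 ± 0.15 and the chitinase-like gene Chi3l1 by 0.37 ± 0.12. Nptx1, Cyp4f17, Gnat2, Grap and Srcap lay between 0.27 and 0.41. On the lower side were Klri1, a natural killer receptor gene (-0.40 ± 0.12), Mir3561 (-0.39 ± 0.13), Agpat2, an acyltransferase of triglyceride synthesis (-0.34 ± 0.12), Zc2hc1b (-0.34 ± 0.11) and Mir134 (-0.32 ± 0.11). Gbp5 was the remaining gene. Il1rn had a mean of 4.508 in lean sham and 5.185 in VSG (log2), and Klri1 read 4.08 or less in every lean sham array. Both were near or below the background control rows, which averaged 4.577 to 5.015 over the arrays. Relative to the lean sham mean, 19 of the 20 differences had the same direction in all 6 VSG arrays and Samd9l in 5. The choice by p in these arrays makes this likely too.

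Over the whole design, no gene differed among the 3 groups in the F test of limma (smallest adjusted p = 0.948), and 345 genes had an unadjusted p below 0.05, or 641 without obese sham replicate 6. The Y-linked gene Uty ranged from 7.97 to 9.31 over the 18 arrays without separate levels, so the sex of the samples could not be read from it. It stood at 8.85 ± 0.30 in lean sham, 8.58 ± 0.40 in obese sham and 8.83 ± 0.18 in VSG (log2, SD) and did not pass the test (adjusted p = 0.798, 0.73 and 1 in the 3 comparisons).

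To place the VSG placentas between the sham groups, the 200 genes with the smallest p between obese and lean sham, of which none had passed the test, were followed into VSG. The median of the difference of VSG from lean sham over that of obese from lean sham was 0.355 (interquartile range 0.191 to 0.553), where 0 is the lean sham level and 1 the obese sham level. When the 18 arrays were regrouped at random 40 times, the same median ranged from 0.196 to 0.866 around 0.499, so the observed value lay within what unchanged groups gave. Over all 18166 genes, the difference of obese from lean sham and that of VSG from obese sham correlated at r = -0.833, with genes not being independent replicates. Both differences share the obese sham arrays, and random regrouping gave -0.873 to -0.0274. The covariance was -0.0339, against -0.0418 to -0.000578 with random groups. With the obese sham arrays split 3 and 3, and each part used in 1 of the differences, the correlation ranged over the 20 splits from -0.183 to 0.1 and the covariance from -0.0088 to 0.00685. Without obese sham replicate 5 the observed correlation was -0.6 and the covariance -0.0102, and the position was 0.462. Random regrouping without that array gave correlations of -0.82 to -0.213 around -0.625 and covariances of -0.0369 to -0.00313. Splits of the remaining obese sham arrays gave correlations of -0.241 to 0.313. Without obese sham replicate 6 the position was 0.217.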

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

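The tests of the array set, of leukocytes, of RNA quality and of obese sham replicate 5 were chosen after the results had been seen. The rule for picking out outlying arrays was fixed in advance, but the values it was run on were not. These were measures of each array, the lists called by camera and the genes named in the text. Within each group of 6 arrays, the highest or lowest array was picked out where its gap to the nearest other array, divided by the range of the group, was above Dixon's 95% critical value, a criterion that chance meets in about 1 of 20 groups. Of 438 groups of values tested, 63 met it, where 21.9 would be expected by chance from independent values. Of the 63, 38 lay in obese sham replicate 5 and 25 in other arrays. Lists and genes that obese sham replicate 5 had moved were among the values tested, so these counts partly reflect how the values were chosen.

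Obese sham replicate 5 stood apart in many placental genes at once. Its list means, relative to the mean of all genes (log2), were below the other obese sham arrays for labyrinth trophoblast (1.42 against 2.89 or more), endothelium (0.427), glucose and amino acid transporters (0.827), insulin and IGF axis (0.78), imprinted genes (1.09), extracellular matrix (0.686), circadian clock (0.145) and hypoxia and glycolysis (1.63). They were above the others for the respiratory chain (2.48 against 1.84 or less) and the cytosolic ribosome (3.6 against 2.82 or less). Genes below the other obese sham arrays in it (log2 level) were Kcnk6 at 6.32, Slc6a6 at 6.55, Slc7a2 at 7.03, Gata1 at 6.34, Zim1 at 7.67, Slc22a3 at 5.86, Slc7a5 at 7.76, Fn1 at 9.72, Nid1 at 7.38, Igf1r at 6.23 and Pgr at 4.73. Below them too were Bmp2 (5.72), Pfkp (7.27), Hk2 (7.31), Clock (7.31), Tie1 (5.81), Gjb2 (9.68) and Srebf2 (6.6). Rps15al4 (9.79), Npm1-ps9 (7.94), Rps19 (11.2), Rps14 (11.5), Atp5po (9.61), Cd209fl1 (5.89), RT1-Da (6.35) and the carboxypeptidase gene Cpa1 (6.7) lay above the other obese sham arrays. The interquartile range of all its values was 2.17 against 2.64 to 2.7 in the others, and its median correlation with the other arrays was 0.877 against 0.975 to 0.982.

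A piece from another zone of the placenta could give such a shift, as could less or degraded RNA in that sample. Its poly-A spike-in rows averaged 8.65 on the log2 scale, 1.35 above the next highest array, while the other 17 arrays spanned 0.827, which is what less or degraded sample RNA would give. Genes used in all cell types differed from the other obese sham arrays by a median of 1.14 (log2), where the highest value of another array was 0.224, which argues against another zone of the placenta as the whole cause. Both tests were made on the array that prompted them, no label records RNA quality per sample, and no biological explanation was tested for a single array.

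Other arrays differed in fewer values. Lean sham replicate 5 was high in the yolk sac list (3.23 against -0.113 to 1.02), cholesterol synthesis (1.44), hypoxia and glycolysis (2.41), Tst (7.95), Bmal1 (7.23), the growth factor receptor gene Met (7.75 against 5.75 to 5.98) and Dhcr7 (9, against 7.62 to 8.01), and low in Tie1 (7.83) and Tap1 (6.76). Lean sham replicate 6 was high in the respiratory chain list (1.87) and Slc22a3 (7.84) and low in Slc6a6 (8.57) and Klri1 (3.54). Lean sham replicate 4 was low in Loxl3 (6.41) and Hgf (4.72), and lean sham replicate 3 was high in RT1-Da (5.92). VSG replicate 4 was high in the labyrinth list (3.15 against 2.91 to 2.93), VSG replicate 5 was low in the circadian clock list (1, against 1.11 to 1.17), VSG replicate 6 was low in Gata1 (6.46), VSG replicate 3 was high in Grik2 (5.27), VSG replicate 2 was high in Ablim3 (6.6) and low in the transferrin receptor gene Tfrc (10.4 against 11.5 to 12), and VSG replicate 1 was low in Mid2 (6.93). Obese sham replicate 2 was high in Ablim3 (6.23) and obese sham replicate 1 was low in Cyp4f17 (5.55).

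The poly-A spike-in rows, which the comparisons did not use, read above the lean sham range of 6.49 to 6.72 (log2) in VSG replicates 1 (6.77) and 5 (6.99) and in obese sham replicates 3 (7.3), 5 (8.65) and 6 (6.74).

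The higher interferon response and antigen presentation lists in VSG than in lean sham could reflect the uneven array sets, less or degraded RNA in some samples, or more leukocytes in the VSG samples. With the array set as a term, 81.7% of the difference in the interferon list was left (0.189 ± 0.0929, SE) and 113% of that in the antigen presentation list (0.126 ± 0.029). With the spike-in mean as a term over the 17 arrays without obese sham replicate 5, 83.5% (0.193 ± 0.111) and 90.6% (0.101 ± 0.0349) were left. For antigen presentation the 113% left with the array set argues against the sets as the whole cause. The 90.6% left with the spike-in mean was also more than 1 SE above 50% of the difference. The spike-in mean is only 1 indirect measure of the RNA, so that value does not exclude the RNA. For the interferon list neither can be told apart from an effect of the group, since what was left lay within 1 SE of 50% of the difference. Of the lower erythroid list 98.4% was left with the spike-in mean as a term (-0.37 ± 0.233), again too wide a spread to exclude the RNA. The macrophage list was at 0.02 (adjusted p = 0.924) and the natural killer, T and B cell lists were not called, while the neutrophil list was called up in the same comparison, so a change in leukocytes cannot be told apart from one within cells by these markers. A response to the operation, named by the design, stays open as untested, and so does a grouping by chance, since 23 of 100 splits of the 12 arrays gave at least as many called lists.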

How the results depend on the processing

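The blocks by array set, the permutation test of lists and the yolk sac covariate were chosen after the data had been seen. The count of genes was 0 in all 3 comparisons and in the F test under every alternative run at an adjusted p below 0.05 or 0.1, with 1 exception: with the array set as a block and obese sham replicate 5 left out, 1 gene passed between obese and lean sham (Hmgn2l1, 0.50, adjusted p = 0.0441). Hmgn2l1 lay near background, with group means of 4.676 to 5.224 (log2), where the background control rows averaged 4.577 to 5.015. At an unadjusted p below 0.05 with a fold of at least 1.5 there were 45, 51 and 15 genes for obese against lean sham, VSG against obese sham and VSG against lean sham, and 48 among the 3 groups. These counts ran from 13 (without obese sham replicate 5, 9 higher and 4 lower, against 16 and 29 over all arrays) to 118 (obese sham replicate 6), from 17 (obese sham replicate 5) to 137 (obese sham replicate 6) and from 8 (VSG replicate 5) to 26 (lean sham replicate 5). The number of shifted lists was 0 in all 3 comparisons by camera with an estimated correlation, by fry and by the exact permutation test. For VSG against obese sham, 3 lists were called with array weights and 20 with the array set as a block. When each array was left out in turn, the counts of lists ran from 8 (obese sham replicate 5) to 15 for obese against lean sham, from 8 (obese sham replicate 5) to 21 (VSG replicate 4) for VSG against obese sham, and from 3 (VSG replicate 3) to 12 for VSG against lean sham. The position of VSG ran from 0.217 (without obese sham replicate 6) to 0.462. The cause was not tested.

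Direction, taken from the camera test and not from the sign of the mean, turned for lists as follows; the cause was not tested beyond the array left out. Between obese and lean sham, array weights gave 0.00772 for the endothelium, 0.0788 for the insulin list and 0.111 for the matrix, Uty as a covariate gave 0.0356 and 0.0257 for the insulin and matrix lists, and the set block without obese sham replicate 5 gave 0.0281, 0.0791 and 0.0691 for the labyrinth, insulin and matrix lists. Leaving out each array gave -0.304 to 0.0215 for the labyrinth, -0.233 to 0.0813 for the insulin list and -0.343 to 0.072 for the matrix. Between VSG and obese sham, array weights gave -0.0266, -0.0328 and -0.041 for the labyrinth, insulin and matrix lists, the mean of the matrix list was 0.0329 with Uty as a covariate while camera pointed down, and the set block without obese sham replicate 5 gave -0.0234 for the matrix. Leaving out each array gave -0.0325 to 0.282 for the insulin list and -0.0297 to 0.385 for the matrix. Between VSG and lean sham, cholesterol synthesis was at 0.00831 with array weights and ran from -0.145 to 0.00703 with each array left out. Of the 352 gene values, 3 turned: Rps14 for VSG against obese sham (0.022 with the set block without obese sham replicate 5) and, for VSG against lean sham, Met (0.0561 with array weights, and -0.274 to 0.126 with each array left out) and Tfrc (-0.228 to 0.0979 with each array left out). Of the other settings of single lists, 803 kept direction and call and 226 kept direction and lost the call. Among the latter the mean changed sign for the labyrinth between obese and lean sham with array weights (0.0202). Between VSG and obese sham it changed sign for the labyrinth without obese sham replicate 5 (-0.0249, or -0.04 with the set block) and the insulin list with the set block without that array (-0.0274).

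The replicate number as a block (replicate block) gave 0 genes in each comparison and 12, 12 and 10 lists, with 880, 889 and 254 genes at an unadjusted p below 0.05. Deviations of same-numbered arrays from their group means correlated at -0.331 to 0.483, above 0.1 in 9 of 14 pairs within 1 array set and 1 of 4 across sets. An array correlated best with its own number in 10 of 36 cases. No label gives the numbers a meaning and not every pair was above 0.1, so they were not taken to pair the samples. Signal over background limits dim genes: with 14419 genes at a mean of 5 or more the gene counts were also 0.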

Other observations

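Several placental functions did not pass the list test in any comparison over all arrays without a block for the array set. Fatty acid oxidation genes, which burn lipid in mitochondria, differed by 0.04 between obese and lean sham, by -0.01 between VSG and obese sham and by 0.02 between VSG and lean sham (log2, relative to the other genes). Steroid hormone synthesis differed by -0.03, -0.03 and -0.05, cell cycle genes by 0.04, -0.00457 and 0.03. Values for the unfolded protein and amino acid stress list were 0.02, -0.04 and -0.02. Adipokines and their receptors differed by 0.04, -0.07 and -0.03, lower than the obese sham mean in 6 of 6 VSG arrays, with an exact two-sided permutation p of 0.143. Junctional zone and glycogen trophoblast genes differed by 0.05, -0.01 and 0.04. With the block, fatty acid oxidation and cell cycle were past the test between VSG and obese sham, pointing down (adjusted p = 0.0203 and 0.0422, and 0.918 and 0.926 over all arrays with an estimated correlation). The junctional zone list was past it between obese and lean sham without obese sham replicate 5 (0.0808, adjusted p = 0.0399, and adjusted p = 0.706 with an estimated correlation). With both changes together, junctional zone, fatty acid oxidation and cell cycle were past it upward between obese and lean sham (adjusted p = 0.0486, 0.00599 and 0.0234), and fatty acid oxidation, cell cycle and the unfolded protein list downward between VSG and obese sham (0.000876, 0.00689 and 0.0269). With an estimated correlation, without that array and with no block, the adjusted p was 0.706, 0.782 and 0.884 for the first 3 and 0.932, 0.932 and 0.771 for the others.

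How often other splits of the arrays gave results as large was fixed in advance; of the tests of gastric-type genes below, that of the array set was chosen after the result had been seen. With 100 splits of the 12 arrays of each pair, the real one included, 57 gave at least the 13 lists of obese against lean sham (highest other 27), 64 at least the 12 of VSG against obese sham (highest other 27) and 23 at least the 10 of VSG against lean sham (highest other 19), so chance cannot be excluded for any of the 3 counts. For genes, with 0 called, all 100 splits had to give as many in each comparison and over the 3 groups (highest other 0, 785, 1 and 0). That count decides nothing about chance. At an unadjusted p below 0.05, 54, 52, 63 and 63 of the 100 splits gave at least the real 618, 713, 182 and 345 genes (highest other 2781, 4808, 3777 and 2772), and chance cannot be excluded. For VSG against obese sham, 5 splits placed all 4 set 2 arrays of those groups on 1 side and called 0, 0, 0, 1 and 785 genes, with 1670 to 4808 genes at an unadjusted p below 0.05 against a median of 727 over the other 99. Another split, with 1 set 2 array on 1 side and 3 on the other, called 1 gene. The split with 1 gene for VSG against lean sham placed all 5 set 2 arrays on 1 side. The split with 785 genes points to a structure of the samples. It followed the array sets, while other splits that followed them called 1 gene or none.

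Genes of gastric type varied widely between arrays within groups, and were picked out after their values were seen. Over the 17 arrays without obese sham replicate 5, the pepsinogen gene Pgc ranged from 5.77 to 11.4 (log2), the gastrokines Gkn1 from 4.9 to 10.3 and Gkn2 from 5.86 to 10.2, the trefoil factor Tff1 from 6.06 to 9.03 and the secreted phospholipase Pla2g1b from 6.01 to 11. All 6 arrays of set 2 were low, with highest values of 6.3, 5.57, 6.28, 6.76 and 6.82. The mean of the 5 genes ran from 7.85 to 10.4 in lean sham replicates 1 to 4, from 6.52 to 9.69 in obese sham replicates 1 to 4 and from 7.35 to 8.58 in VSG replicates 1 to 3.

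Stomach or pancreas tissue carried into some samples could give this pattern, as could the array set. The mean of 11 measured genes of gastric acid and mucus, fixed before the test, ranged over 12.8% of the range of the gastric-type mean (5.48 to 6.06, log2), with the proton pump genes Atp4a at 6.3 to 7.07 and Atp4b at 6.15 to 8. The mean of 12 exocrine pancreas genes ranged over 10% of it (5.38 to 5.84), with Cpa1 at 5.45 to 5.81 and Cela1 at 5.83 to 6.48. These genes thus varied far less, but the percentages cannot exclude either tissue, because the 5 gastric-type genes were picked for varying. Without obese sham replicate 5, both lists were highest in lean sham replicate 4 (6.06 and 5.84), which also had the highest gastric-type mean (10.4). With obese sham replicate 5 left out, every set 2 array had a gastric-type mean of 6.18 or less and every set 1 array 6.52 or more. Within set 1 this mean ranged over 3.88, against 0.321 within set 2. The set thus goes with part of the variation and does not account for the spread within set 1. A source within the uterus or placenta, such as the amount of a maternal or fetal epithelium in the piece taken, may remain and was not tested, and the hypothesis that these genes mark such a tissue rests on these arrays alone.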
